A study of Mus musculus with 4 samples.

How the data were processed

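The samples were 4 cultures or RNA preparations of mouse embryonic fibroblasts, 2 labelled Med1+/+ p53-/- and 2 labelled Med1-/- p53-/-, grouped by the genotype in their labels. Per the labels' protocols, total RNA was labelled with biotin by in vitro transcription with the 3' IVT Express Kit of Affymetrix. The deposited table held 1 linear signal intensity per probe set and array. How the authors summarised probes into probe sets, corrected the background or scaled the arrays is not given in the sources used here. The 75th percentile of the deposited intensity was 362.1 and 507.6 on the Med1+/+ arrays and 193.3 and 281.3 on the Med1-/- arrays, so the arrays did not share a scale, and by a rule fixed before the data were examined they were quantile normalized. The fixed test needed no change for this unit.

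The 64 control probe sets were left out of normalization and tests, which used the other 22626. Gene symbols came from the platform annotation, updated through Entrez identifiers in the RefSeq gene table of assembly GRCm38.p6, from which gene neighbourhoods, chromosomes and genomic lengths were also taken. 20380 probe sets had 1 symbol, 691 several and 1555 none, and the first kind covered 12393 genes; a probe set with several symbols or none was tested under its own identifier and given no gene name. The planned values for Spp1 and Trp53 are not reported here.

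Normalized intensities were taken as log2(value + 1.7), the pseudocount being the 10th percentile of the table. Fold changes are on that scale, which understates the change of dim genes. Probe sets with a mean under the 40th percentile were left out, which removed 9050, and for a gene with several probe sets the one with the highest mean was used. For none of the 156 genes that the naming rule gave did another probe set pass the test in the opposite direction. Probe sets with _s_at or _x_at identifiers can match transcripts of other genes, and among the genes named here those of Xist, Hmgcs1, Tgm2, Dlk1, Angptl4, Ndn, Mt1, Itga5, Egfl7, Gpm6a and Wt1 were of this kind. Med1-/- was compared with Med1+/+ by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over 8923 features and a threshold of 0.05. The fit had 2 residual and 4.71 prior degrees of freedom.

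In all, 43 lists of pathway genes, cell type markers, Med1 neighbours and sex-linked genes were written before the data were examined. The 39 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation (lowest adjusted p = 0.726) and with fry, which called 29. Fry's directional test asks whether the genes of a list move on balance one way and does not compare the list with other genes. The genes named in the text were fixed by rule beforehand, except where a sentence says otherwise: Med1, Trp53 and Spp1, the 12 largest rises and 12 largest falls among called genes that separated the genotypes, and in each list described up to 4 called members with the largest change. The text names fewer than 4 in most lists, and 1 unnamed probe set rose and 2 fell by as much as the genes in the top 12.

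The procedure was tested on simulated data built from these arrays, for the comparison of Med1-/- with Med1+/+. In it 200 genes were changed before the filter, a further list of 30 genes was moved as a whole, and 8925 genes were tested. It recovered 35.5% of changes of 0.5 log2, 93.2% of changes of 1 and 100% of changes of 2, with 23 false calls among 183. That share of false calls was above the threshold of 0.05, in the 1 simulation run. The list moved as a whole was called (adjusted p = 2.36e-72, camera in limma) along with 0 of 38 lists left unmoved, but with an estimated correlation the moved list was missed (adjusted p = 0.0948) in the 1 simulation run. Noise was drawn independently for each gene and few genes were changed, unlike in the data. The simulation therefore does not show how often camera calls unmoved lists here.

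Alternatives fixed beforehand varied the filter, the scaling between arrays, the pseudocount, the choice of probe set, the variance model, array weights, a replicate block, the arrays left out, the thresholds and the list test. Added after the data were seen were an adjustment for gene density and genomic length (splines of each array's deviation from the gene mean), scaling on the 75th percentile, on the hybridisation controls and on the Bacillus subtilis controls, and the removal of genes of chromosomes 13 and X. Gene density was the number of protein-coding genes in a fixed window around a gene, known for 88.2% of the features. Bootstrap intervals used 2000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.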

Results

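Gene expression was measured in mouse embryonic fibroblasts, mesenchymal cells grown out of embryos, that lacked p53 and either carried or lacked Med1. Med1 encodes a subunit of Mediator, the complex that links DNA-bound transcription factors, among them nuclear hormone receptors, to RNA polymerase II. The fibroblasts came from mid-gestation embryos of a C57BL/6J cross that, per the labels, yielded both genotypes. Total RNA was labelled with biotin and hybridised to 3'-biased Affymetrix arrays with 22626 probe sets besides controls, on 2 arrays per genotype. The deposited values were linear signals that had not been brought to a common scale: the median signal was 76.25 and 106.65 on the Med1+/+ arrays and 36.1 and 51.4 on the Med1-/- arrays. With 4 arrays in all, the number of arrays limits the precision of every value. The labels do not say that the 2 arrays of a genotype came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

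Med1 signal was nearly lost in the Med1-/- cells. On the brightest Med1 probe set, 1448708_at, the deposited signal was 664.6 and 885.6 on the Med1+/+ arrays and 25.4 and 40.2 on the Med1-/- arrays, a log2 change of -3.57 (SE 0.14, n = 2 per genotype; adjusted p = 3.15e-05, limma with Benjamini-Hochberg adjustment). A second probe set above the expression filter, 1421907_at, changed by -2.82. The other 4 Med1 probe sets had means below the expression filter and log2 differences from -2.26 to -0.30. All 6 thus ran in the direction of the labels, although the sources do not state where the deletion lies relative to each probe set.

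**Figure D1:**
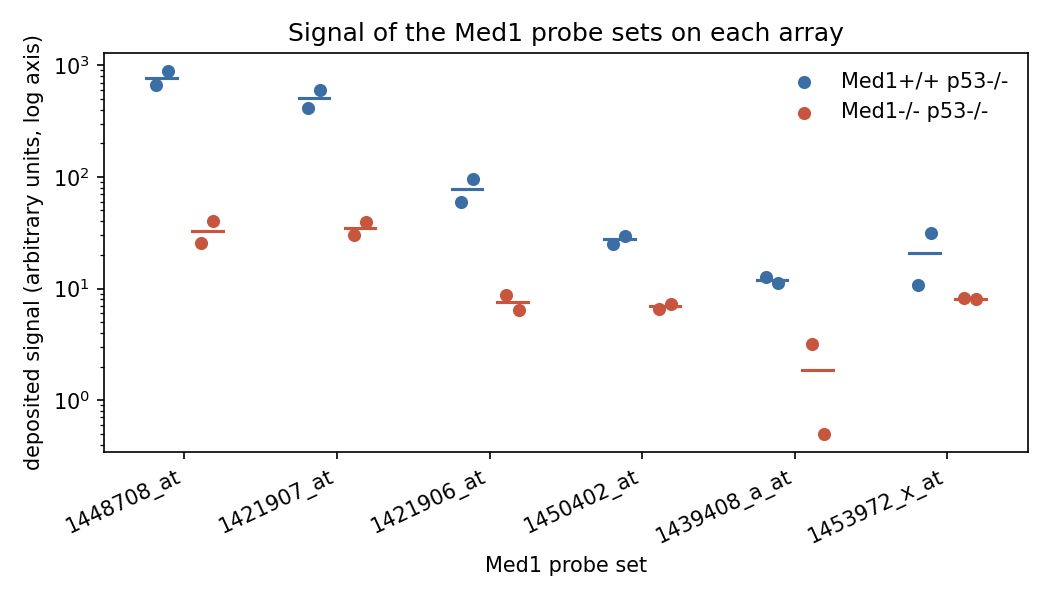
Deposited signal of the 6 Med1 probe sets (log axis) on the Med1+/+ p53-/- arrays (blue) and the Med1-/- p53-/- arrays (red). Points are single arrays, bars are means of 2 arrays, and probe set 1448708_at read 664.6 and 885.6 in Med1+/+ cells against 25.4 and 40.2 in Med1-/- cells.

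The comparison of Med1-/- with Med1+/+ cells asked which genes differ between the genotypes. The study's title points to the support of blood stem and progenitor cells through osteopontin. Other differences between the embryos or cultures behind each genotype cannot be told apart from the loss of Med1, for any gene or list below. Fxyd6 and the smooth muscle actin gene Actg2 had the largest rises in Med1-/- cells, and Fgf13 and Fgf7 the largest falls. Contractile and immediate early genes were higher as lists, and interferon-stimulated, cytokine, cholesterol synthesis and stromal factor genes lower, by camera in limma with a preset correlation. None of these 6 list calls held with an estimated correlation (lowest adjusted p = 0.726), and the stromal call was also lost after adjustment for gene density and length (adjusted p = 0.14). The version with an estimated correlation also missed a list moved as a whole in the simulation (adjusted p = 0.0948, camera in limma). It may lack power with these arrays, so it does not decide whether the calls hold. The genotypes differed across most of the expressed genome. Of 8923 features tested (7874 named genes and 1049 probe sets not assigned to a single gene), 3490 were higher and 3232 were lower in Med1-/- cells at an adjusted p under 0.05, and 1890 and 1715 of these differed at least 2-fold. The median absolute log2 change was 0.836, against a median absolute difference between replicates of 0.144 in Med1+/+ and 0.166 in Med1-/- cells. Across genes, arrays of the same genotype correlated at 0.990 (Med1+/+) and 0.985 (Med1-/-), and arrays of different genotypes at 0.823 to 0.836. The balance of higher against lower calls was set by the scaling of the arrays. Of the calls 51.9% were higher after quantile normalization, 59.9% with array medians set equal and 52.9% with 75th percentiles set equal. The share was 6.4% in the values as deposited, 17.8% after scaling on the hybridisation controls and 1.0% after scaling on the Bacillus subtilis control transcripts. In the same order, the median log2 change of all features was 0.09, 0.298, 0.113, -0.757, -0.782 and -1.72. In the values as deposited 29 of the named genes lost their call and 8 reversed. All changes below are from quantile normalized values, so they are relative to the other genes on the arrays.

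Fxyd6, a regulator of the sodium pump, had the largest rise, with a log2 change of 6.35 (SE 0.34, n = 2 per genotype; adjusted p = 3.15e-05, limma with Benjamini-Hochberg adjustment). Its signal in Med1+/+ cells lay near the pseudocount, which limits how exactly its fold can be read. Actg2, the enteric smooth muscle actin, rose from a mean log2 value of 5.91 ± 0.0059 to 11.3 ± 0.018 (SD, n = 2), a 42.1-fold difference. Cnn1, which encodes the smooth muscle protein calponin, rose 17.0-fold, the skeletal actin gene Acta1 20.3-fold and the muscle intermediate filament gene Des 13.7-fold. The other genes among the 12 largest rises were Stmn4 (log2 change 4.55), which encodes a neuronal microtubule regulator, the angiogenic factor gene Pgf (3.98), the retinoic acid synthesis gene Aldh1a2 (3.82), the focal adhesion gene Lims2 (3.66) and the developmental transcription factor genes Foxd1 (3.59), Six2 (3.55) and Pitx1 (3.52).

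The 12 largest falls included the fibroblast growth factor genes Fgf13 (log2 change -4.83) and Fgf7 (-4.82), the steroid-metabolising reductase gene Akr1c14 (-4.77) and the neutrophil chemokine gene Cxcl5 (-4.63). Xist, the RNA that coats the inactive X chromosome, fell by 4.53 on its brightest probe set, where the deposited signal was 6724 and 7500 in Med1+/+ and 211.2 and 159.6 in Med1-/- cells. The epithelial genes Cdh1 (-4.50), which encodes E-cadherin, Krt18 (-4.45), a keratin gene, and Dsg2 (-4.39), a desmosomal cadherin gene, fell together with Bex2 (-4.40), the collagenase gene Mmp13 (-4.37), the retinoic acid binding protein gene Crabp1 (-4.31) and the tetraspanin gene Tspan8 (-4.29). The dimmer genotype had a mean log2 value under 4 for Fxyd6 (1.90), Stmn4 (3.51), Pgf (3.58), Akr1c14 (3.22), Fgf7 (3.27), Mmp13 (3.77) and Fgf13 (3.96), so that the size and rank of these changes are inexact. Of all features, 88.2% had both values of one genotype beyond both of the other, against 33.3% by chance; the 24 genes were chosen among these. Adjusted p-values over the 24 ran from 6.39e-06 for Actg2 to 0.000381 for Pgf (limma with Benjamini-Hochberg adjustment).

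Genes of interferon response and cytokine signalling were lower in Med1-/- cells. Of 32 interferon-stimulated genes tested, 21 fell and 5 rose. The guanylate-binding GTPase genes Gbp2 (log2 change -3.91) and Gbp3 (-3.31), the antiviral gene Rsad2 (-3.26) and Rtp4 (-3.04) had the largest falls. As a list these genes were lower than the other genes (median log2 change -1.29; adjusted p = 0.00566, camera in limma with a preset correlation and Benjamini-Hochberg adjustment; adjusted p = 0.726 with an estimated correlation). The cytokine list shared a member with the interferon list, and Csf1, Cxcl12, Il6 and Lif with the stromal factor list below. These list calls are therefore not separate findings. Of 18 cytokine and chemokine genes, 13 fell and 2 rose. The falls included Cxcl15 (-3.26) and the monocyte chemoattractant genes Ccl2 (-3.16) and Ccl7 (-2.78), and the list had a median of -1.84 (adjusted p = 0.00906, camera in limma; adjusted p = 0.726 with an estimated correlation). In the same cells 5 of 10 epithelial markers were lower and 2 higher, the largest falls being those of Cdh1 (-4.50), Krt18 (-4.45), Dsg2 (-4.39) and Dsp (-3.92), although that list did not pass (adjusted p = 0.34, camera in limma).

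Cholesterol synthesis genes were lower as well, with 14 falling and 3 rising of 20 tested. Idi1 (log2 change -3.52), Hmgcs1 (-3.22) and Msmo1 (-2.73), which encode enzymes of the mevalonate and sterol pathways, and the sterol carrier gene Stard4 (-2.14) changed most. The list had a median of -0.886 (adjusted p = 0.0167, camera in limma; adjusted p = 0.726 with an estimated correlation). The epithelial genes Cdh1, Krt18, Dsg2 and Dsp fell in the same cells, although the epithelial list did not pass (adjusted p = 0.34, camera in limma). A link between them and the sterol genes was not tested.

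Genes listed as stromal factors for blood stem and progenitor cells were mostly lower in Med1-/- cells, with 13 falling and 4 rising of 22 tested. The matrix protein gene Mgp (log2 change -4.13, SE 0.19), the growth factor binding protein gene Igfbp2 (-3.47, SE 0.15), the heparin-binding cytokine gene Ptn (-3.40) and the Notch ligand family gene Dlk1 (-3.20) fell most. Among members outside the naming rule, chosen after their values were seen, Kitl, the ligand of Kit (-2.06), Cxcl12, the ligand of Cxcr4 (-1.91), and Il6 (-1.78) fell. The 4 that rose were Angptl4 (2.49), Tnc (1.02), Csf1 (0.89) and Ndn (0.35), and Jag1 (-1.11), Igf1 (-0.94), Lif (-0.04), Fn1 (0.16) and Wnt5a (0.19) did not pass. The list had a median of -1.15 (adjusted p = 0.0344, camera in limma; adjusted p = 0.726 with an estimated correlation), and its call was lost when gene density and gene length were adjusted for (adjusted p = 0.14). Spp1, the osteopontin gene, and Trp53 are not analysed here. Of 12 osteoblast and bone matrix genes, 4 were higher and 5 lower, among the latter Postn (-3.84) and the osteoblast cadherin gene Cdh11 (-2.13), and the list did not pass (adjusted p = 0.684, camera in limma; the median was 0.151 and the mean -0.795). Markers of fibroblasts and mesenchyme moved both ways beside these lists, with 6 higher and 4 lower of 13. The largest called changes among them were falls, those of Pdgfra (-2.95), Prrx1 (-2.89) and S100a4 (-2.68). Relative to all genes the median of these markers was -0.00361 after quantile normalization and 0.507 to 0.521 under the other scalings.

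Contractile and immediate early genes were higher in Med1-/- cells. Of 16 contractile and myofibroblast genes 13 rose and 2 fell, with Smtn, which encodes smoothelin, rising by 2.40 behind Actg2, Cnn1 and Des. This list had a median of 1.18 (adjusted p = 0.00566, camera in limma with a preset correlation, and 0.754 with an estimated correlation). Its estimated correlation was 0.48, against the preset 0.01 and -0.032 to 0.07 for the other called lists. The preset test is therefore less secure for this list than for the others. Skeletal muscle markers moved beside the contractile list, with 4 higher and 0 lower of 6 tested among 21 on the array, including Actc1 (2.01). Cardiac muscle markers had 4 higher and 0 lower of 5 tested among 19 on the array, including Nppb (2.39). Neither marker list passed (adjusted p = 0.169 and 0.168, camera in limma). These lists share genes: Tnnt2 is in both marker lists, and Des is in the skeletal and contractile lists. The contractile and immediate early lists also share a member. The filter used the mean of all arrays, so a marker bright in Med1-/- cells alone could pass it. Of 28 immediate early and serum response genes, 20 rose and 5 fell. The transcription factor genes Etv4 (2.02) and Jund (1.76) and the growth factor signalling inhibitor gene Spry1 (1.89) rose, whereas Klf6 fell by 1.86. The list had a median of 1.13 (adjusted p = 0.00906, camera in limma; adjusted p = 0.726 with an estimated correlation). Under scaling on the Bacillus subtilis controls the medians of the contractile and immediate early lists were -0.273 and -0.656, still above the median of all genes.

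**Figure D2:**
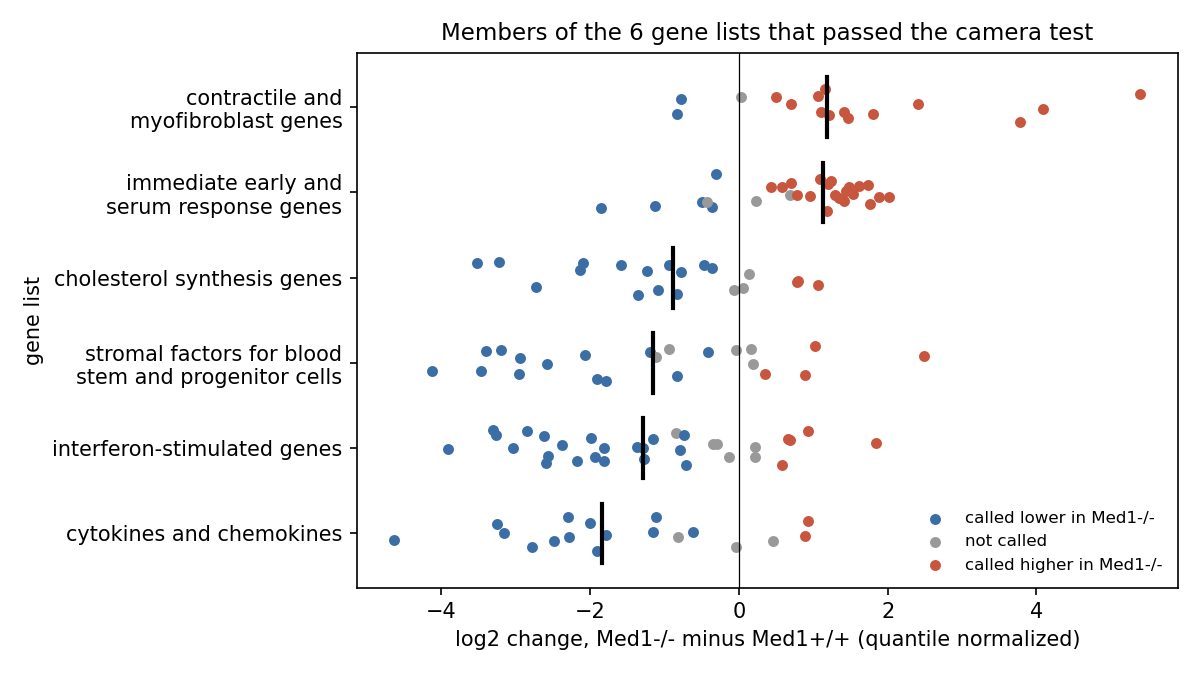
Log2 change (Med1-/- minus Med1+/+, quantile normalized) of each tested member of the 6 gene lists that passed camera, with points coloured by the call of the gene and jittered vertically, and black bars at list medians. Medians ran from -1.84 for cytokines and chemokines to 1.18 for contractile genes, and each list had members that ran against its median; under scaling on the Bacillus subtilis controls the medians of the contractile and immediate early lists were below 0.

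Med1 is known as a contact of nuclear receptors, and the lists of their pathways did not pass as lists. Of 9 vitamin D receptor pathway genes 4 were higher and 3 lower, the receptor gene Vdr itself rising by 2.05 and Igfbp3 falling by 1.76 (list adjusted p = 0.826, camera in limma). Of 10 thyroid hormone response genes 5 were higher and 1 lower, the latter being Klf9 (-1.73). Adipogenesis genes had 9 higher and 4 lower of 15, with Klf5 (1.85), the lipid droplet gene Plin2 (1.65) and Dgat2 (1.59) higher. Glucocorticoid response genes had 6 higher and 7 lower of 16, the metallothionein genes Mt2 (-2.23) and Mt1 (-1.64) being lower. Retinoic acid response genes had 4 higher and 6 lower of 13, with Aldh1a1 (-4.13) lower and Tgm2 (3.37) higher. The lowest adjusted p of these lists was 0.529, for the retinoic acid list (camera in limma). Of 27 other Mediator subunit genes, 12 were higher, including Med15 (1.92), Med25 (1.57) and Med16 (1.43), and 10 were lower, including Med6 (-1.75) (adjusted p = 0.684, camera in limma).

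Developmental genes moved in both directions. Of 18 Hox genes, which specify position along the body axis, 11 were higher and 3 lower, with Hoxb9 (log2 change 2.72), Hoxc9 (2.24), Hoxd9 (1.92) and Hoxc8 (1.66) higher (adjusted p = 0.169, camera in limma). Imprinted genes had 12 lower and 4 higher of 16, Igf2 (-2.58) and Dcn (-1.99) being lower (adjusted p = 0.07, camera in limma), and after adjustment for gene density and length 6 were lower and 4 higher (adjusted p = 0.61). Wnt pathway genes had 12 higher and 7 lower of 26, with the antagonist gene Sfrp2 (-3.95) lower and Wnt11 (2.40) and Rspo1 (2.11) higher. Notch pathway genes had 7 higher and 1 lower of 12, Lfng (3.08, dim in Med1+/+ cells) and the ligand gene Jag2 (1.84) being higher. TGF-beta and BMP pathway genes had 12 higher and 15 lower of 35, Fstl3 (3.29) being higher and the BMP antagonist gene Grem1 (-2.65) lower. Insulin-like growth factor axis genes had 4 higher and 7 lower of 14. Among neural and neural crest markers 3 of 6 were higher, including Nes (2.08), and 1 lower. None of these lists passed camera.

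Housekeeping, cell cycle and stress lists did not pass camera either (lowest adjusted p = 0.34 in limma, for the G2 and mitosis and the unfolded protein response lists). S phase genes had 17 higher and 13 lower of 37, and G2 and mitosis genes 14 higher and 22 lower of 44, with Cenpf (log2 change -1.92) and Top2a (-1.78) lower and Plk1 (1.85) higher. Of 23 p53 target genes 9 were higher and 11 lower in these p53-deficient cells, Cdkn1a (2.58) being higher and Trp53inp1 (-4.13, dim in Med1-/- cells) lower. Hypoxia and glycolysis genes had 9 higher and 10 lower of 28, Pdk1 (-3.76) and Bnip3 (-2.55) being lower. Oxidative phosphorylation genes had 16 higher and 19 lower of 45, unfolded protein response genes 17 higher, including Atf5 (2.32), and 8 lower of 31, and oxidative stress genes 10 higher and 10 lower of 26, the glutathione transferase genes Mgst1 (-3.14) and Gsta4 (-3.08) being lower. Ribosomal protein genes had 4 higher and 11 lower of 31 (adjusted p = 0.36, camera in limma), and after adjustment for gene density and length this list was called (adjusted p = 0.00104; adjusted p = 0.66 with an estimated correlation on the adjusted values). The direction depended on the scaling: relative to all genes the median of the ribosomal list was -0.261 after quantile normalization and 0.263 to 0.284 under the other 5 scalings, and that of the oxidative phosphorylation list was -0.117 and 0.213 to 0.233. The same held for the fibroblast and mesenchyme markers (-0.00361, and 0.507 to 0.521 under the others), the osteoblast list (0.0615, and -0.175 to -0.113) and the p53 targets (0.0187, and -0.0734 to -0.0695). Collagens and matrix proteins had 19 higher and 14 lower of 40, with Ogn (-3.46) lower, matrix proteases and inhibitors 10 higher and 8 lower of 23, and integrins 4 higher, including Itga5 (2.48), and 3 lower, including Itga6 (-2.45), of 8. Median and mean change differed in sign for the collagen, protease, p53 target, TGF-beta, hypoxia, oxidative stress and fibroblast marker lists, and for integrins the direction of the test was opposite to both. Counts adjusted over the list alone differed by at most 3 genes in any direction from these; for the called lists they added 1 lower gene to the stromal and 1 to the cytokine list.

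Gene position went with the direction of change. Genes in gene-dense regions tended to be higher in Med1-/- cells and genes in gene-poor regions lower, with medians from -0.633 in the fifth of genes with fewest neighbours to 0.803 in the fifth with most (Spearman's rho 0.439 across 7866 genes, which are not independent replicates). Genes of chromosome 13 and of chromosome X were shifted down, by medians of -1.06 and -0.806 relative to all genes, and by -0.672 (95% bootstrap interval -0.827 to -0.536) and -0.505 (-0.648 to -0.379) after adjustment for gene density and length. Of 24 genes near Med1 on chromosome 11, 14 were higher and 5 lower (adjusted p = 0.357, camera in limma), and after the same adjustment 9 were higher and 9 lower. Without the genes of chromosomes 13 and X, 3397 features were higher and 2901 lower. Adjustment for gene density and length left 3185 higher and 2934 lower, and 78.5% of the original calls kept their direction and call.

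**Figure D3:**
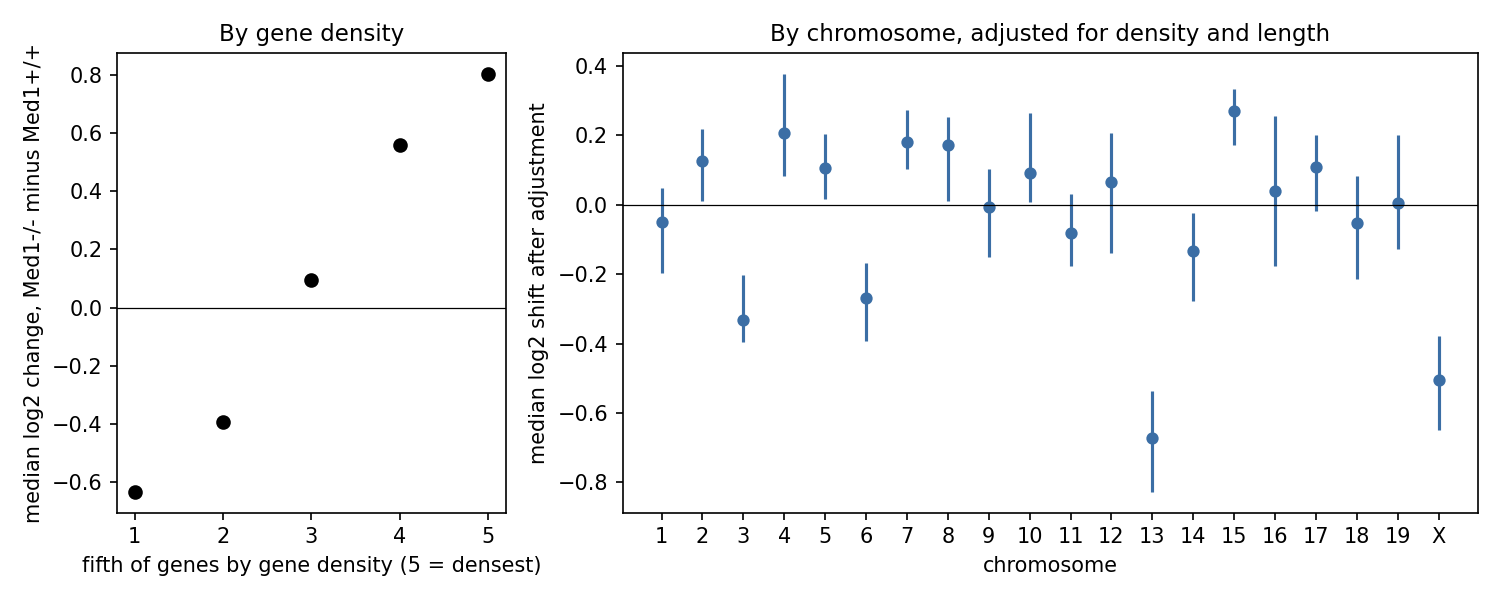
Left, median log2 change (Med1-/- minus Med1+/+) in 5 groups of genes ordered by the number of neighbouring genes, rising from -0.633 to 0.803. Right, median log2 shift of the genes of each chromosome after adjustment for gene density and length, with 95% bootstrap intervals over genes; chromosome 13 (-0.672) and chromosome X (-0.505) lay lowest.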

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

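The tests of array brightness against gene density, of the normalization and of dim probe sets were set up before their results were seen; the tests on control probe sets, chromosome 13, chromosome X and Y-linked genes were chosen after, and that of chromosome 13 copies was made stricter once its values were known. Control probe sets, which entered no comparison, stood out because several kinds were higher on both Med1-/- arrays than on both Med1+/+ arrays. The median log2 difference of deposited signals was 1.12 for dap, 0.916 for lys, 0.975 for phe and 0.84 for thr, transcripts of Bacillus subtilis that are used as labelling controls. It was 1.25 for the probe set of the B1 repeat, a short interspersed element present in many mouse transcripts, and -0.0434 for the 2 probe sets of the B2 repeat, which were not higher.

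The bacterial controls were brighter while the mouse genes were dimmer on the Med1-/- arrays: all 24 of their probe sets were higher, by a median of 0.99, whereas the tested genes had a median of -0.752 in the same deposited signals. Weaker hybridisation or scanning is argued against, since the median gene lay lower against the hybridisation controls bioB, bioC, bioD and cre by a log2 difference of -0.916 (SE 0.127), and more degraded RNA is argued against by the 3' to 5' signal ratios of Actb and Gapdh, of which the higher change was 0.192 (SE 0.0788). Less messenger RNA per total RNA in the Med1-/- samples and more control transcript added to them cannot be told apart, because both give the same shift of the controls against the genes, 1.74. If the former holds, a scaling on these controls may be the fitting one and most genes would be lower; quantile normalization then gives only relative changes. An effect of the Med1 genotype on messenger RNA content remains possible and was not tested.

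The trend with gene density was present with rho 0.439 across genes. The quantile normalization as its source is argued against by a rho of 0.442 when only the array medians were set equal, and dim probe sets by a rho of 0.457 among the brighter part of the genes. Array brightness or labelling yield stays open and cannot be told apart from genotype. The dimmer minus the brighter replicate had a rho of 0.113 in Med1+/+ and 0.0327 in Med1-/- cells. The latter met the rule set beforehand against this source, a rho under 0.05 in either genotype. Its upper 95% bound was 0.0548. Judging by that bound, which takes genes as independent, was not part of the rule. Replicates differed in hybridisation (0.481 and 0.494 log2 in the hybridisation controls), so they do not test labelling. The Med1 genotype may also produce such a trend, which these arrays do not test separately.

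Genes of chromosome 13 were lower beyond the density trend, with an adjusted median shift of -0.672 that lay below that of all other autosomes (the next was -0.332), which argues against the trend as the whole source. Fewer copies of chromosome 13 in the Med1-/- culture stay open: the lowest share of genes below the genome-wide median over 5 runs along the chromosome was 59.6%, but the median shift of the runs was uneven, from -1.01 to -0.235, the last with an interval that included 0 (-0.535 to 0.113), and 1 of the 18 other autosomes, chromosome 3, also had most genes below the median in each run (at least 58.2%). For chromosome X the adjusted shift was -0.505, also beyond the trend, and Xist fell. A Y chromosome in the Med1-/- cells alone cannot be told apart from the loss of an X chromosome or of Xist expression, because the 6 Y-linked probe sets (median log2 difference -0.45) were dim on all arrays, with signals of at most 11.4. The Med1 genotype, and differences between the embryos or cultures behind each genotype, stay open and were not tested.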

How the results depend on the processing

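Density adjustment, control and 75th percentile scaling and the removal of chromosomes 13 and X were chosen after the data were seen. Over 155 named genes other than Med1, chosen because they were called, and 20 settings, 2928 values kept direction and call, 75 kept direction but lost the call and 12 reversed. Settings that changed only the threshold or the variance model could not change a direction. Genes below a filter gave no value: the 60th percentile filter covered 100 of the 155. Fxyd6 had no value there or in the deposited scale. Med1 stayed called and lower in each setting that gave calls per gene. Its log2 change was -4.54 under scaling on hybridisation controls and -5.46 on Bacillus subtilis controls. Control scaling gave no calls per gene, and the removal of chromosomes gave counts only. In the deposited scale 265 features were higher (the cause was not tested), and Bcl3 (-0.32), Me1 (-0.36), Gata6 (-0.011), Eng (-0.21), Runx1 (-0.35), Cd14 (-0.45), Cd34 (-0.26) and Wt1 (-0.076) reversed. With array medians equal Rps4x (0.058) and Rpl4 (0.017) reversed, and with the density adjustment Cd14 (-0.14) and Foxa2 (0.013); the cause was not tested. Scaling on hybridisation controls gave 1168 higher and 5391 lower features, and on Bacillus subtilis controls 77 and 7956. At least 2-fold changes numbered 1890 higher and 1715 lower, by construction. Lists called numbered 3 with the 60th percentile filter (fewer genes tested), 0 with an estimated correlation (also 0 in camera at an unadjusted p under 0.05) and 29 with fry, which asks another question. The version with an estimated correlation missed a moved list in the simulation, so its 0 calls do not show that no list differs.

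Leaving out 1 array at a time, with the lone array assumed to vary like the other genotype, gave 3077 to 3341 higher and 2710 to 3171 lower features, 6 to 7 lists and a Med1 change of -3.65 to -3.47; 5723 to 6185 of the 6722 calls were kept. A replicate block gave 3825 higher and 3500 lower and shared 6709 of the 6722 calls. The labels do not say that replicate numbers pair the samples. Hybridisation controls were nonetheless alike within a replicate number across genotypes. For bioB the Med1+/+ and Med1-/- signals were 305.4 and 312.6 for replicate 1, and 449.8 and 472.7 for replicate 2. Whether same-numbered arrays were processed together is not stated. Deviations of same-numbered replicates correlated at 0.27 across genes, 0.034 without a filter, 0.47 with the 60th percentile filter, 0.32 with the 30th percentile pseudocount, 0.25 with the mean of probe sets and 0.30 over every probe set; the cause was not tested. Signal over background was low for genes near the pseudocount, which limits their folds. No value for Spp1 is given under any setting.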

Other observations

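The marker lists not described in the report differed in how many members passed the expression filter. Of 17 endothelial markers on the array 4 were tested, 2 being higher, among them Egfl7 (log2 change 1.86), and 1 lower. Of 23 blood and macrophage markers on the array 5 were tested, with 3 higher and 0 lower. Of 8 mesothelial and epicardial markers on the array 7 were tested, with 3 higher, including Krt19 (1.61), and 4 lower, including Gpm6a (-1.68). Extraembryonic and pluripotent cell markers had 1 higher, Dab2 (1.24), and 1 lower of 5 tested among 20 on the array. Of 18 cartilage markers on the array 1 was tested and lower, Sox9 (-0.49, adjusted p = 0.0276, limma with Benjamini-Hochberg adjustment), a call that was lost without Med1+/+ replicate 1 (-0.42), without Med1+/+ replicate 2 (-0.57) and without Med1-/- replicate 1 (-0.34), with no expression filter (adjusted p = 0.057 in limma) and after adjustment for gene density and length (-0.093, adjusted p = 0.615 in limma). None of the lists among these with at least 5 tested genes passed camera in limma (lowest adjusted p = 0.34).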
